A study of Helianthemum marifolium subsp. andalusicum and Helianthemum marifolium subsp. marifolium and Helianthemum marifolium subsp. molle with 16 samples.

How the data were processed

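Poly-A RNA from adult leaves of 4 subspecies of Helianthemum marifolium was sequenced in 16 libraries, 4 per subspecies, per the labels' protocols. The authors deposited a table of raw counts, with 1 column of whole-number counts for each library and 1 row for each cluster of assembled transcripts, and a list that pairs each transcript name with its cluster. Per the submitters' processing notes, FastQC was among the tools. The assembler, the clustering tool, the aligner and the counter, with their versions, are not given in the sources used here, nor is the strandedness. No reference genome or annotation was used here. The deposited list has 122009 transcripts in 2 naming styles, 70183 of the form that Trinity writes and 51826 of the form that Oases writes, the latter with the numbers 25 and 31 and with a length in nt. Cluster names have the form that Corset writes. These are resemblances of names only. In all, 18108 transcripts stand under 1 name that has no counts and were left out. Of the 100462 counted clusters, 96.8% hold 1 transcript, and a gene can be split over several clusters: by the assemblers' own gene names the clusters fall into 91651 genes, with 1 group of 1566 linked clusters kept separate. Reads shared between such clusters, between paralogs or between alleles may have been split or assigned to 1 of them, and without stated strand-specific counting antisense transcripts cannot be told apart.

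The counts were used as deposited. Every column was matched to a library by its title, and 0 columns were left unmatched. Libraries were grouped by the subspecies in their labels. No library pair of a subspecies agreed within sampling noise, since chi-square per degree of freedom over clusters ran from 89.8 to 215.5. The library numbers in the titles are not shared between subspecies. Differences between subspecies were tested in R 4.3.3 with edgeR 4.0.16 (TMM normalisation, filterByExpr by subspecies, quasi-likelihood F-test, Benjamini-Hochberg adjusted p under 0.05) on all 16 libraries. The filter kept 46027 clusters and left out 54435. The kept clusters held between 95.8% and 99.4% of a library's counts. The common dispersion was 1.10, a biological coefficient of variation of 105%. Each subspecies was compared with the unweighted mean of the other 3 on the log2 scale, and with each of the others, and all 4 were compared together. Under such a contrast a cluster can be called when it is absent from 1 or 2 other subspecies alone. The 2 title codes of a subspecies were compared in a model with 8 codes of 2 libraries. Fold changes are on the log2 scale with the standard error from the F statistic. For a cluster at 0 in all libraries of a group, the fold sets the mean of the libraries on the other side against a floor of 3 counts over that group. It is a lower bound for counting error in that group only, and single libraries can lie much nearer to the floor than the mean.

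Distances were Euclidean over log2 CPM (prior count 2), divided by the square root of the number of clusters, with exact permutation tests. A cluster counted as present at 10 or more counts in each library and as absent at 0. Thinning drew 22170314 counts from each library without replacement (seed 1, numpy 2.4.6). Intervals for shares are 95% Wilson intervals (scipy 1.17.1) and cover counting error only, since the reads carry no molecular identifiers.

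The rule for naming single clusters was written before the data were examined. For each subspecies against the others and each direction it took annotated clusters with an adjusted p under 0.05, a mean of at least 1 CPM and all 4 libraries beyond all 12 others, and among them the 5 with the largest change and the 5 with the smallest p. Where the files pair no names with clusters, as here, it allows at most 2 identifiers that rose and 2 that fell, and does not say how to pick them. The pick was made after the data were examined: under the same criteria, the cluster with the largest fitted change, and then the one with the smallest p of the remaining, were taken in each comparison and direction. Identifiers were printed for the largest fitted change over the 4 comparisons in each direction and then for the smallest p of those remaining. In total, 32 gene lists were also fixed beforehand, for tests with camera. They could not be applied because the files pair no names with clusters, so no list has a result here.

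The edgeR test was checked on counts simulated from the real means, dispersions and library sizes of the 46027 clusters, with 200 clusters changed in 1 subspecies, for each of the 4 subspecies against the others. Over the 4 simulations, 36% of 8-fold increases and 19% of 8-fold decreases were called, 87% of 64-fold increases and 37% of 64-fold decreases, and 1% of 2-fold changes in either direction. Unchanged clusters made up 7.21% of the calls. The counting of present and absent clusters and the distance tests were also checked on data with planted patterns.

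Alternatives fixed beforehand were DESeq2 size factors in place of TMM, DESeq2 1.42.0 in place of edgeR, no filter on low counts, at least 1 CPM in 8 libraries, each library left out, counts summed per title code, limma 3.58.1 voom with the code as a random block, clusters at 0 in all of a subspecies left out, counts summed per assembler gene, only the 8 libraries of a pair, other prior counts and Spearman correlation for distances, and other minimums for presence. Alternatives added after seeing the data left out both marifolium libraries 12 and 18, or the clusters with over 95% of their counts in them, used edgeR's robust dispersion, and counted present clusters per assembler gene or after thinning. The pairings of subspecies, with the same alternatives, were also examined after seeing the data. To ask how often other groupings of the libraries give as many calls, 100 regroupings of the 16 libraries into 4 groups of 4 were fitted, the real one included. For the 4 subspecies together this was repeated with 100 ways of joining the 8 title codes in pairs, which keep the libraries of a code together.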

Results

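Leaf transcriptomes of Helianthemum marifolium, a dwarf shrub of the Cistaceae, were profiled by poly-A RNA sequencing in its 4 subspecies, andalusicum, marifolium, molle and origanifolium. Each subspecies had 4 libraries, all from adult leaves of greenhouse plants grown from seed and sampled at day 446 after sowing. The sample titles carry a code shared by 2 libraries of a subspecies, so that the 16 libraries fall under 8 codes. What the code marks is not given in the sources used here. The libraries are named below by subspecies and by the library number in the title. The labels do not say that libraries came from separate plants, so the p-values measure the spread between these libraries, part of which may be technical. The title of the series names adaptive mechanisms as the subject of study, and the comparisons below ask which transcripts set each subspecies apart in leaves under a shared growth environment.

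The count table held 100462 clusters of assembled transcripts. Counts summed to 22170314 in origanifolium 31 and to 34121011 in molle 22, the lowest and highest of the 16 libraries. The mean total was 29880497 ± 2508059 counts in andalusicum, 30478222 ± 947334 in marifolium, 30764839 ± 3492057 in molle and 26232773 ± 4221855 in origanifolium (SD, n = 4 each). A count of 0 in a library allows up to 0.0879 counts-per-million (CPM) in the deepest library and up to 0.135 CPM in the shallowest, which covers counting error only. In all, 18896 clusters had at least 10 counts in every library, and these held 92.9% of all counts. The files pair no gene names with the clusters, so the clusters are described by their levels, and identifiers are printed for 4 of them. The other clusters described singly were chosen by a criterion set after the files were seen to lack names.

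Libraries grouped by subspecies and, within a subspecies, mostly by title code. Each of the 16 libraries had its nearest neighbour in its own subspecies, and 14 had it in their own code. The exceptions were marifolium 17 and 18, which share a code but were each nearest to marifolium 12, of the other marifolium code. The mean distance (root mean square difference of log2 CPM over 46027 tested clusters) was 1.89 between libraries of the same code, 2.04 between libraries of the same subspecies with different codes, and 2.35 between subspecies. Same-code distances were the smallest among all 81 ways of pairing libraries within subspecies (exact permutation test, one-sided p = 0.0123, the smallest it can give). Distances between libraries of different codes of a subspecies were the smallest among all ways of joining the 8 codes in pairs (exact permutation test, one-sided p = 0.00952, the smallest it can give). Pairs of libraries of the same code did not enter that test. Libraries of origanifolium lay closest together, at a mean of 1.85 ± 0.0659 over 6 pairs, and those of marifolium furthest apart, at 2.22 ± 0.138 (SD over pairs, which share libraries). Between subspecies, the mean distance ran from 2.24 ± 0.0796 for andalusicum and molle to 2.47 ± 0.128 for andalusicum and marifolium (SD over 16 pairs). Molle and origanifolium lay at 2.26 ± 0.0378, closer than marifolium and origanifolium at 2.32 ± 0.144.

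**Figure D1:**
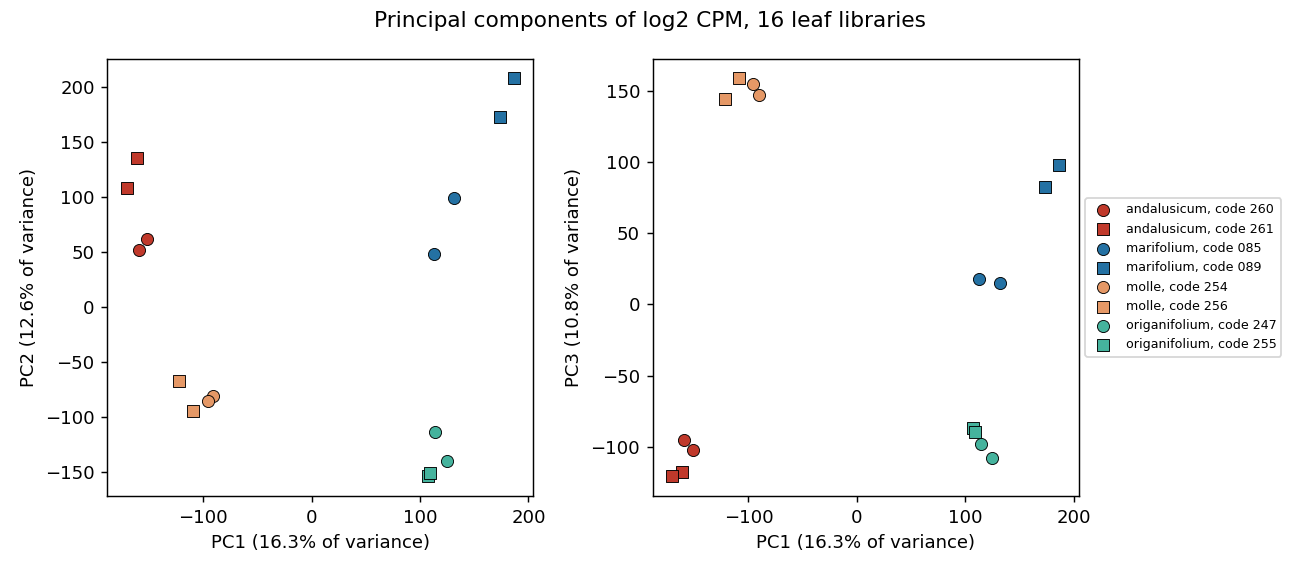
Principal components of log2 CPM for 16 leaf libraries, coloured by subspecies with the 2 title codes of each as circles and squares; the axes give the percentage of variance. The first component (16.3%) separates andalusicum and molle from marifolium and origanifolium, and the second and the third hold 12.6% and 10.8%.

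Across the 4 subspecies together, 2661 of the 46027 tested clusters differed (edgeR quasi-likelihood F-test, Benjamini-Hochberg adjusted p under 0.05). With clusters at 0 in all 4 libraries of any subspecies left out, 944 of 39884 differed. DESeq2 called 7393, limma voom with the code as a random block called 4359, and 19 were called when the 2 libraries of each code were summed. Among clusters with at least 1 CPM in 8 libraries 1422 were called. Without origanifolium 39 there were 1655, and without marifolium 12 and 18 there were 1739.

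Andalusicum differed from the mean of the other 3 subspecies in 1745 clusters, of which 1393 were higher and 352 lower in andalusicum (edgeR, adjusted p under 0.05). In 411 of the higher and 136 of the lower clusters, all 4 andalusicum libraries lay beyond all 12 others. Over all tested clusters, whatever their p, the libraries were separated in this way in 544 clusters upward and 182 downward, where random order would give 25.3 in each direction. That number takes libraries of the same title code as independent, although they lie closer together. Among the higher clusters, 832 had no count in any library of at least 1 other subspecies, and 80 had none in any of the 12 other libraries. The largest increase was in Cluster-3823.43744, an assembled transcript of 1482 nt, which stood at 44.7 ± 34.2 CPM in andalusicum (SD, n = 4) and had 0 counts in the 12 other libraries against 5330 in andalusicum. Set against a floor of 3 counts over the 12 libraries, its mean was at least 5141-fold higher in andalusicum, and its 4 libraries ranged from 6.46 to 87.9 CPM (edgeR adjusted p = 0.000931). Its call was lost with the libraries of each code summed (edgeR adjusted p = 0.0538, the highest of 25 alternatives, the lowest being 2.71e-06). The increase with the smallest p was in a cluster expressed in every subspecies, at 104 ± 36.8 CPM in andalusicum and 13.6 ± 3.80 CPM over the 12 others (log2 fold change 2.93 ± 0.23 SE, edgeR adjusted p = 1.46e-05). This cluster had close levels in the other subspecies, 12.98 ± 5.54 CPM in marifolium, 13.5 ± 1.37 in molle and 14.3 ± 4.36 in origanifolium. The largest decrease was in a transcript of 2285 nt with 0 counts in andalusicum and 21.9 ± 13.5 CPM in the others (n = 12), by the mean at least 862-fold lower. Among the others it ran from 0.699 CPM in marifolium 15 to 54.6 CPM in molle 29. A further cluster fell by 2.39 ± 0.21 on the log2 scale, from 104 ± 34.7 CPM in the others to 19.1 ± 2.52 CPM in andalusicum (edgeR adjusted p = 2.14e-05). Of the higher clusters 27, and of the lower 55, were also called against each of the other 3 subspecies alone. DESeq2 called 4106 clusters (2242 higher, 1864 lower), 424 were called with clusters at 0 in all of a subspecies left out, 54 with the libraries of each code summed, and between 987 and 1127 without 1 of the andalusicum libraries. Among clusters with at least 1 CPM in 8 libraries 675 were called (405 higher, 270 lower), and 1159 were called without marifolium 12 and 18.

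Marifolium differed from the other 3 subspecies in 1034 clusters, 709 of them higher and 325 lower (edgeR, adjusted p under 0.05). All 4 libraries lay beyond the 12 others in 186 of the higher and 140 of the lower clusters. Absence was frequent among the decreases, where 169 of the 325 clusters had 0 counts in all 4 marifolium libraries. The increase with the smallest p was in Cluster-3823.67090, at 96.7 ± 20.8 CPM in marifolium (n = 4) and 1.19 ± 0.650 CPM in the others (n = 12), a log2 fold change of 6.37 ± 0.40 SE (edgeR adjusted p = 8.26e-07). Its lowest marifolium library stood at 75.5 CPM and its highest library elsewhere at 2.47 CPM. Cluster-3823.44903, a transcript of 1913 nt, had 0 counts in marifolium and 15.0 ± 3.24 CPM in the others, at least 596-fold lower in marifolium (edgeR adjusted p = 3.39e-07). Its levels were even across the other subspecies, at 12.1 ± 2.38 CPM in andalusicum, 17.7 ± 3.21 in molle and 15.2 ± 1.32 in origanifolium. A further cluster with 0 counts in marifolium stood at 10.6 ± 4.66 CPM in the others and was at least 420.4-fold lower (edgeR adjusted p = 3.62e-05). It lost its call with the libraries of each code summed (edgeR adjusted p = 0.0615, the highest of 26 alternatives, the lowest being 1.1e-19). The largest increase was in a transcript of 4935 nt that was at 0 in all 12 other libraries and varied widely within marifolium (mean 23.7 ± 29.4 CPM). It stood at 27.2 and 64.0 CPM in marifolium 12 and 18, and at 1.32 and 2.49 CPM in marifolium 15 and 17. It lost its call with the libraries of each code summed (edgeR adjusted p = 0.0738) and without marifolium 12 and 18 (0.112), over a range from 0.000774 to 0.112 in 24 alternatives. Of the higher clusters 6, and of the lower 46, were also called against each of the other subspecies alone. Marifolium libraries 12 and 18 carried 1.60% (95% Wilson interval 1.598 to 1.607) and 2.52% (2.512 to 2.523) of their counts in 6240 clusters with over 95% of their counts in these libraries, against at most 0.00570% in any other library. A low share elsewhere is fixed by how these clusters were picked, and the pick favours a call for marifolium. Only 11 of these clusters were among the 46027 tested, and 10 of the 11 were among the calls, including the transcript of 4935 nt with the largest increase. Leaving out both libraries gave 185 calls. DESeq2 called 4272 (1759 higher, 2513 lower), 377 were called among clusters with at least 1 CPM in 8 libraries, 9493 without a filter on low counts (8733 higher, 760 lower), 180 with clusters at 0 in all of a subspecies left out, 19 with the libraries of each code summed, and 662, 634 and 534 without marifolium 12, 17 or 18, 688 without andalusicum 3, and 682 and 645 without origanifolium 38 or 39.

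Molle differed from the others in 1114 clusters, 904 higher and 210 lower (edgeR, adjusted p under 0.05). All 4 molle libraries lay beyond the other 12 in 279 of the higher and 78 of the lower clusters. The largest decrease was in Cluster-3823.41664, which had 0 counts in the 4 molle libraries and 26625 in the others, at 75.0 ± 35.3 CPM (n = 12), and was thus at least 3053-fold lower in molle (edgeR adjusted p = 2.16e-07). It was present in every other library, at 68.4 ± 16.7 CPM in andalusicum, 108 ± 41.9 in marifolium and 48.4 ± 8.40 in origanifolium. A second cluster with 0 counts in molle stood at 9.94 ± 3.87 CPM elsewhere and was at least 405-fold lower (edgeR adjusted p = 2.23e-05). Among the increases, a transcript of 1509 nt had 2622 counts in molle, at 22.1 ± 15.1 CPM, and 1 count in the 12 other libraries together. The increase with the smallest p was graded: it stood at 57.1 ± 14.9 CPM in molle, 19.6 ± 4.20 CPM in andalusicum and 0 in marifolium, with 0.0201 ± 0.0402 CPM in origanifolium (edgeR adjusted p = 1.56e-06). Of the higher clusters 24, and of the lower 23, were also called against each of the other subspecies alone. DESeq2 called 3539 (1655 higher, 1884 lower), 296 were called with clusters at 0 in all of a subspecies left out, 49 with the libraries of each code summed, and between 565 and 697 without 1 of the molle libraries. Among clusters with at least 1 CPM in 8 libraries 545 were called, and 727 were called without marifolium 12 and 18.

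Origanifolium differed from the others in 1571 clusters, 1278 higher and 293 lower (edgeR, adjusted p under 0.05). Its 4 libraries lay beyond the other 12 in 432 of the higher and 89 of the lower clusters, and over all tested clusters in 707 upward and 137 downward. The increase with the smallest p was in a cluster at 29.8 ± 13.7 CPM in origanifolium and 1.96 ± 0.821 CPM in the others, a log2 fold change of 3.96 ± 0.34 SE (edgeR adjusted p = 5.66e-05). The largest increase rested unevenly on the libraries, with 104.9 CPM in origanifolium 38 and 6.21 to 15.9 CPM in the other three, against 5 counts in the 12 other libraries. Its call was lost with the libraries of each code summed (edgeR adjusted p = 0.111, the highest of 25 alternatives, the lowest being 1.7e-18). The largest decrease was in a cluster with 0 counts in origanifolium and 18.1 ± 16.7 CPM elsewhere, by the mean at least 626-fold lower (edgeR adjusted p = 0.00820). This cluster ran from 0.266 CPM in molle 29 to 55.4 CPM in molle 25. It lost its call with the libraries of each code summed (edgeR adjusted p = 0.104) and with limma voom (0.138), over a range from 2.7e-14 to 0.138 in 26 alternatives. Another had 1 count in origanifolium against 11118 in the others, where it stood at 56.3 ± 14.1 CPM in molle, 32.5 ± 26.5 in andalusicum and 5.48 ± 4.46 in marifolium. Of the higher clusters 9, and of the lower 9, were also called against each of the other subspecies alone. DESeq2 called 4290 (2447 higher, 1843 lower), 694 were called with clusters at 0 in all of a subspecies left out, 20 with the libraries of each code summed, and between 609 and 777 without 1 of the origanifolium libraries. Among clusters with at least 1 CPM in 8 libraries 989 were called, limma voom with the code as a random block called 2426, and 900 were called without marifolium 12 and 18.

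**Figure D2:**
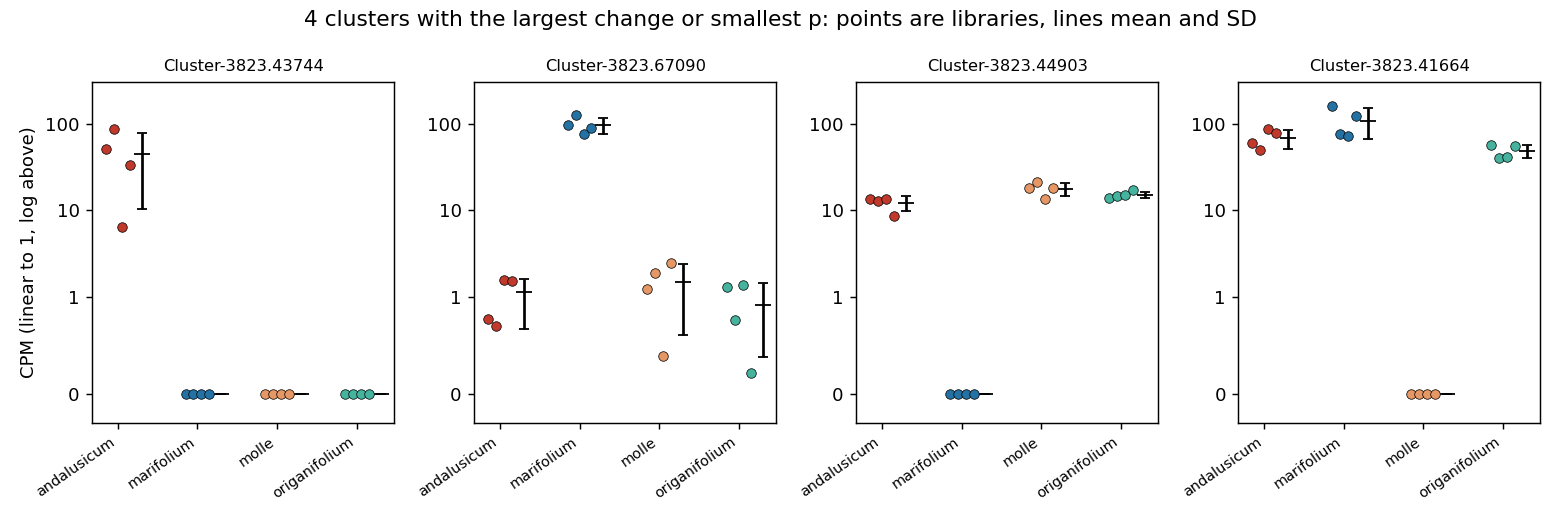
Levels of 4 clusters in 16 libraries, in CPM on an axis that is linear to 1 and logarithmic above; points are libraries, and the lines beside them give the mean and SD of 4. Cluster-3823.43744 was counted in andalusicum alone, and Cluster-3823.67090 was at least 75.5 CPM in marifolium and at most 2.47 CPM elsewhere. Cluster-3823.44903 was at 0 in marifolium alone, and Cluster-3823.41664 was at 0 in molle alone.

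Between pairs of subspecies, edgeR on all 16 libraries called the fewest clusters between marifolium and origanifolium and between andalusicum and molle. In the first pair 124 clusters differed, 34 higher and 90 lower in marifolium, and in the second 201 differed, 97 higher and 104 lower in andalusicum (edgeR, adjusted p under 0.05). The other pairs had more calls. Andalusicum and marifolium differed in 988 clusters (616 higher and 372 lower in andalusicum), andalusicum and origanifolium in 918 (459 in each direction), marifolium and molle in 762 (288 higher and 474 lower in marifolium), and molle and origanifolium in 710 (386 higher and 324 lower in molle). These counts depended on the tool. DESeq2 called 3231 clusters for marifolium and origanifolium and 2772 for andalusicum and molle, the lowest counts it gave, and between 4005 and 4694 for the other pairs. Limma voom with the code as a random block called 1087 for marifolium and origanifolium and 1091 for andalusicum and molle, again its lowest counts, and between 1617 and 2289 for the other pairs. They also depended on the filter. Without a filter on low counts edgeR called 73 for marifolium and origanifolium, 488 for andalusicum and marifolium, 466 for andalusicum and origanifolium, 481 for marifolium and molle and 418 for molle and origanifolium. Among clusters with at least 1 CPM in 8 libraries it called 543 for andalusicum and marifolium and 484 for marifolium and molle. With clusters at 0 in all of a subspecies left out the counts ran from 32 for marifolium and origanifolium to 457 for andalusicum and origanifolium. Without marifolium 12 and 18 there were 19 calls for marifolium and origanifolium, 221 for andalusicum and marifolium and 222 for marifolium and molle. With only the 8 libraries of a pair in the model the counts were 44 for marifolium and origanifolium, 283 for andalusicum and molle, 439 for andalusicum and marifolium, 501 for marifolium and molle, 1082 for molle and origanifolium and 1575 for andalusicum and origanifolium. With the libraries of each code summed, edgeR called 2 clusters for marifolium and origanifolium, 1 for andalusicum and molle, 8 for andalusicum and marifolium, 25 for marifolium and molle, 9 for molle and origanifolium and 0 for andalusicum and origanifolium, so the order of the pairs was not kept. For andalusicum and origanifolium 6068 of the 46027 tested clusters had an unadjusted p under 0.05. Without 1 library the counts fell to as few as 36 (without origanifolium 38) for marifolium and origanifolium, 95 (without molle 25) for andalusicum and molle, 447 (without andalusicum 8) for andalusicum and marifolium, 315 (without origanifolium 38) for andalusicum and origanifolium, 371 (without molle 27) for marifolium and molle and 282 (without origanifolium 33) for molle and origanifolium.

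**Figure D3:**
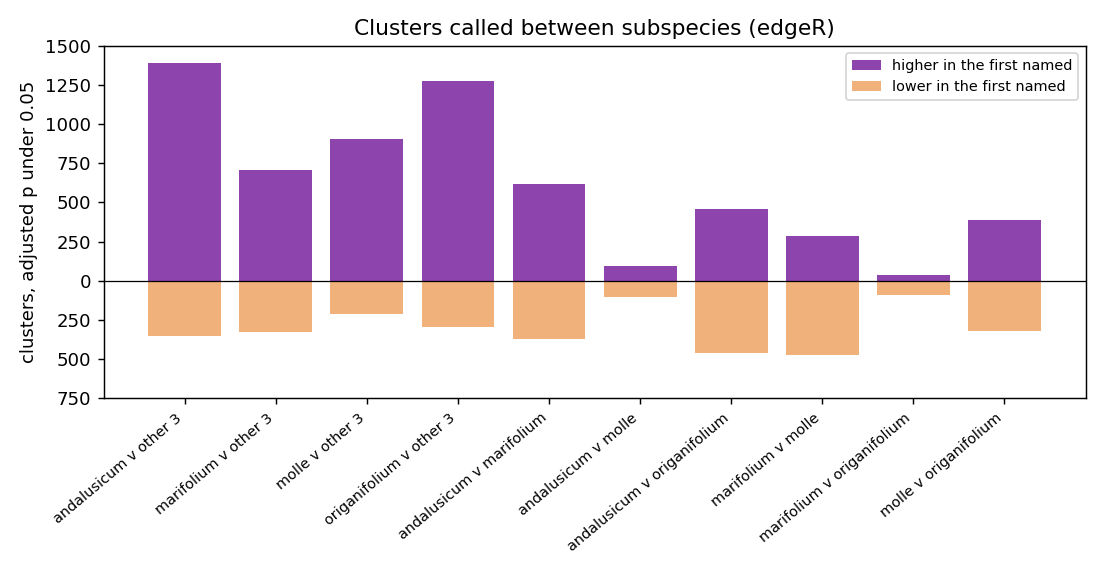
Clusters called by edgeR at an adjusted p under 0.05 in each subspecies against the other 3 and between pairs, as bars above 0 for clusters higher and below 0 for clusters lower in the subspecies named first. Counts run from 124 for marifolium against origanifolium to 1745 for andalusicum against the other 3.

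Few clusters were called between the 2 title codes of a subspecies. With 2 libraries against 2, edgeR called 17 clusters between the codes of andalusicum, 24 in marifolium, 2 in molle and 2 in origanifolium (adjusted p under 0.05). In these comparisons 3548, 5382, 2678 and 2176 of the 46027 tested clusters had an unadjusted p under 0.05 (7.71%, 11.7%, 5.82% and 4.73%). With no differences a share near that threshold would arise by chance, so molle and origanifolium showed little or no excess. The same model applied to codes of different subspecies, again 2 libraries against 2, called between 16 and 292 clusters in 24 comparisons, with a median of 58. There the share with an unadjusted p under 0.05 ran from 9.53% to 18.7%, with a median of 12.3%. The codes of marifolium thus differed about as much as those of some pairs of subspecies. Their 24 calls exceeded the 17 and 21 between 1 of them and the codes of origanifolium. They also exceeded the 23 and 16 between 1 andalusicum code and the codes of molle. With the other marifolium code the counts were 32 and 33, and with the other andalusicum code 59 and 44. Without a filter on low counts the counts between codes rose to 288 in andalusicum, 345 in marifolium, 257 in molle and 159 in origanifolium.

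Some clusters were counted in the libraries of 1 subspecies and nowhere else. With at least 10 counts in each of the 4 libraries and 0 in the 12 others, there were 83 such clusters in andalusicum, 76 in marifolium, 29 in molle and 21 in origanifolium. Among all possible choices of 4 libraries, including those that part libraries of a code, 2 gave at least as many as andalusicum, 3 as many as marifolium, 6 as many as molle and 9 as many as origanifolium, the subspecies included. The highest number, 98, belonged to a choice that follows no subspecies, andalusicum 8 with marifolium 12, 17 and 18. In the reverse direction, 11 clusters were at 0 in andalusicum and at 10 or more counts in each of the 12 others, 11 were so in marifolium, 8 in molle and 0 in origanifolium. No choice of 4 libraries exceeded 11. With a minimum of 20 counts the clusters present in 1 subspecies numbered 49, 31, 16 and 4 in andalusicum, marifolium, molle and origanifolium, and with a minimum of 5 those of origanifolium numbered 57. Leaving out a library can only add clusters, since fewer libraries must meet the criterion. Present clusters numbered 125 without andalusicum 6 for andalusicum, 754 and 259 without marifolium 15 or 17 for marifolium, and 48, 47 and 46 without molle 25, 27 or 29 for molle. Those of origanifolium numbered 33, 45, 36 and 42 without origanifolium 31, 33, 38 or 39. Absent clusters numbered 17 without andalusicum 8 for andalusicum, 20, 20 and 19 without marifolium 12, 15 or 18 for marifolium, 15 without molle 29 for molle and 2 without origanifolium 39 for origanifolium. A count of 0 over the 4 libraries of a subspecies allows up to 0.0244 CPM in molle, the lowest of these limits, and up to 0.0286 CPM in origanifolium, the highest.

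Absence was shared by pairs of subspecies too. Andalusicum and molle shared 30 clusters at 10 or more counts in each of their 8 libraries and 0 in the other 8, and marifolium and origanifolium shared 22, whereas the 4 remaining pairs shared 3, 2, 0 and 1. After thinning every library to 22170314 counts, the numbers were 25 for andalusicum and molle and 17 for marifolium and origanifolium.

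**Figure D4:**
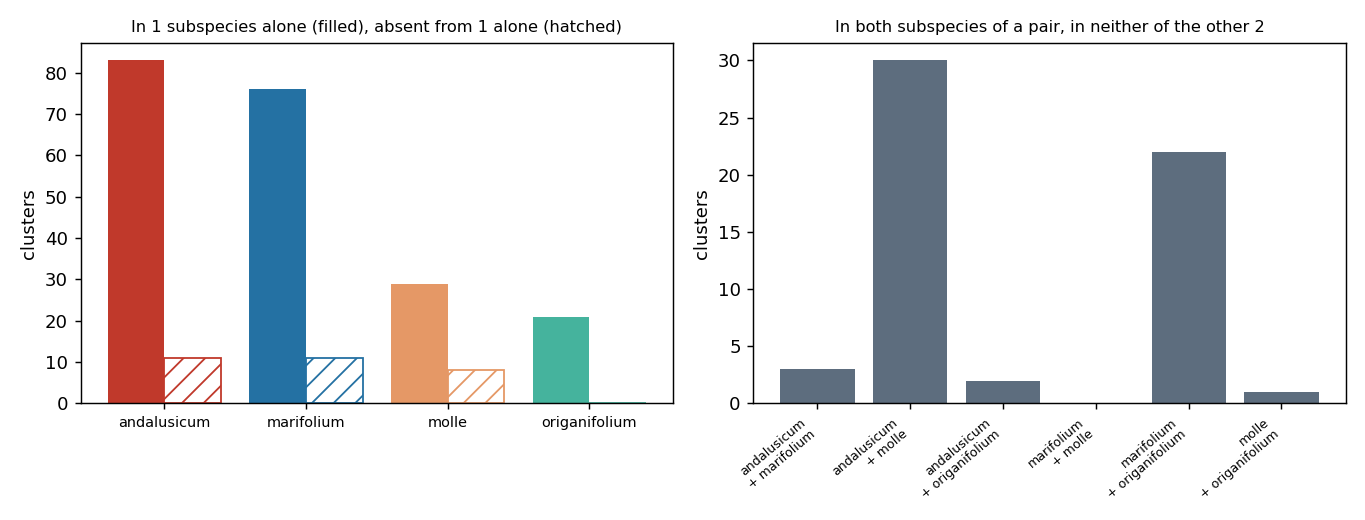
Left, clusters with at least 10 counts in all 4 libraries of a subspecies and 0 elsewhere (filled bars, 83 in andalusicum to 21 in origanifolium) and clusters at 0 in the subspecies and at 10 or more in all others (hatched, 11, 11, 8 and 0). Right, clusters with at least 10 counts in all 8 libraries of a pair of subspecies and 0 in the other 8, with 30 for andalusicum and molle and 22 for marifolium and origanifolium.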

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

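The tests of alleles, of a constant mixture and of RNA of another organism for the clusters of marifolium 12 and 18 were chosen after the result was seen.

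A set of 3411 clusters, outside those tested between subspecies, had at least 10 counts in marifolium 12 and in marifolium 18 and 0 in the 14 other libraries. These 2 libraries carry different title codes. The next pair of libraries, andalusicum 1 and 3, shared 172 such clusters, and after thinning to equal depth the numbers were 3292 and 136. The median count was 69 in marifolium 12 and 113 in marifolium 18. Clusters shared with exactly 1 further library were most frequent for marifolium 17 (662), andalusicum 8 (284), andalusicum 6 (202) and marifolium 15 (183), and at most 31 for any other.

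Variants of a transcript that other libraries also hold are argued against, only as far as the assemblers' names join them, by the share of the set with another cluster of the same assembler gene, 0.352% against 19.3% of clusters present in every library and 7.21% of the 2579 clusters found in another pair of libraries alone. The set and the clusters present in every library also differ in names and lengths, which may affect how often names join clusters. A name of the Trinity form was held by 31.1% against 62.5%, and the median length, where given, was 481 against 1670 nt. RNA of another organism was first tested as a mixture in constant proportions, for which the log2 ratio of marifolium 12 to marifolium 18 would vary less over the set than over clusters present in every library, and it varied more, with an SD of 1.36 against 1.06 (1.29 for such clusters with like counts), which argues against that form. Only after this outcome was the explanation restated as an organism whose own expression differs between the libraries, a form that this SD cannot exclude and that stays open because sequences were not analysed here. Alleles that marifolium 12 and 18 share would leave alternative alleles in the other libraries, and 12 clusters were at 10 or more counts in each of the 14 others and at 0 in both. This number excludes nothing. It falls when an alternative allele is also held by either library or is under 10 counts in any other. In the 8 pairs of libraries that share a title code, such clusters against those present in both alone ran from 1 against 48 (origanifolium 38 and 39) to 64 against 69 (marifolium 17 and 18). Shared alleles thus cannot be told apart from other causes here. A difference between the leaf material of these libraries that the labels do not describe stays open too and was not tested.

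Among 63 groups of 4 values examined for a value far from the rest, 5 had one. Chance flags about 1 in 20 such groups where values are normally distributed. Andalusicum 8 had 40373 clusters with at least 10 counts, against 38039 to 38434 in the other andalusicum libraries. The cluster with the largest increase in origanifolium stood at 104.9 CPM in origanifolium 38 and at 6.21 to 15.9 CPM in the other origanifolium libraries. The remaining values are counts in libraries of a subspecies otherwise at 0. Such a group is flagged whatever the size of the count, so the rate of 1 in 20 does not cover it. They were 0.0322 CPM in andalusicum 1 for the largest increase in molle, 0.0803 CPM in origanifolium 38 for the increase in molle with the smallest p, and 0.0311 CPM in origanifolium 39 for the decrease in origanifolium with the smallest p.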

How the results depend on the processing

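The settings without marifolium 12 and 18, without clusters concentrated in them, with robust dispersion, the present clusters per assembler gene or thinned, and all those of the pairings of subspecies were chosen after seeing the data. DESeq2 size factors, robust dispersion and assembler genes kept each count of clusters called within 1.5 times of its value. Leaving out the clusters concentrated in marifolium 12 and 18 says nothing about stability, since only 11 of them were tested. The distance tests kept their direction and side of the threshold under other prior counts and Spearman correlation. The gene list tests and their alternatives could not be run. No paired analysis was possible because the subspecies share no library numbers. The cause of the changes below was not tested, except that summing per code leaves 2 values per subspecies, and that fewer clusters or libraries enter where these are left out. The order of counts below is the 4 subspecies together, then andalusicum, marifolium, molle and origanifolium against the rest, then the pairs andalusicum with marifolium, molle and origanifolium, marifolium with molle and origanifolium, and molle with origanifolium.

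DESeq2 gave 7393, then 4106, 4272, 3539 and 4290, then 4587, 2772, 4694, 4510, 3231 and 4005, and these held most edgeR calls, such as 1623 of 1745 for andalusicum. Sums per title code gave 19, then 54, 19, 49 and 20, then 8, 1, 0, 25, 2 and 9 (for the 0, andalusicum with origanifolium by edgeR, 6068 of the 46027 tested clusters had an unadjusted p under 0.05, and DESeq2 on all libraries called 4694). Leaving out clusters at 0 in all of a subspecies gave 944, then 424, 180, 296 and 694, then about 2.6e+02, 88, 457, 164, 32 and 356. Without marifolium 12 and 18 the counts that moved were 1739 for the 4 subspecies, 1159, 185, 727 and 900 against the rest, and 221, 222 and 19 for marifolium with andalusicum, molle and origanifolium. Voom with the code as a block (consensus correlation 0.0693) gave 4359 for the 4 subspecies, 2426 for origanifolium against the rest, and 2172, 1091, 2289, 1718, 1087 and 1617 for the pairs. At least 1 CPM in 8 libraries gave 1422, then 675, 377, 545 and 989, with 543 for andalusicum with marifolium and 484 for marifolium with molle. No filter gave 9493 for marifolium against the rest, 488, 466, 481, 73 and 418 for the pairs other than andalusicum with molle, and 288, 345, 257 and 159 between the codes of andalusicum, marifolium, molle and origanifolium. The 8 libraries of a pair alone gave 439, 1575, 501, 44 and 1082, again without andalusicum with molle.

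Leaving out 1 library gave 1655 (without origanifolium 39) to 2590 for the 4 subspecies, 987 to 1699 for andalusicum, 534 to 988 for marifolium, 565 to 1012 for molle and 609 to 1808 for origanifolium against the rest, and 447 to 884, 95 to 240, 315 to 1278, 371 to 799, 36 to 144 and 282 to 959 for the pairs. Counts fell by over 1.5 times without any library of andalusicum (1127, 1096, 1020 and 987 without 1, 3, 6 and 8), molle (697, 639, 583 and 565 without 22, 25, 27 and 29) or origanifolium (699, 777, 632 and 609 without 31, 33, 38 and 39) in their own comparison with the rest, and for marifolium without 12 (662), 17 (634), 18 (534), andalusicum 3 (688) or origanifolium 38 (682) and 39 (645). In the pairs every library of either subspecies did so, except andalusicum 3 with molle and marifolium 15 with molle or origanifolium, and molle 25 did so for marifolium with origanifolium (73).

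For andalusicum and molle against marifolium and origanifolium (2775 clusters), then andalusicum and marifolium (356) and andalusicum and origanifolium (211) against the rest, DESeq2 gave 6015, 3596 and 3034, sums per code 221, 1 and 6, leaving out clusters at 0 in all of a subspecies 921, 122 and 30, and leaving out marifolium 12 and 18 gave 1421, 91 and 47. Voom gave 908 and 752 for the second and the third, no filter gave 1474 for the first and 121 for the third, and at least 1 CPM in 8 libraries gave 1353 for the first. Without 1 library they ran from 1734 to 2380, 163 to 347 and 74 to 191. The first pairing had the most calls of the 3 in each of these settings. Counts fell by over 1.5 times without any origanifolium library for the first, without andalusicum 6 (206), molle 22 (204), 25 (182) or 29 (185) or any origanifolium library (211, 210, 181 and 163 without 31, 33, 38 and 39) for the second, and without any library but marifolium 15 for the third.

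Of 416 values of the 16 clusters described singly, 409 stayed past the threshold, 0 changed sign and 7 no longer passed. Of the 409, 15 come from leaving out the 11 tested clusters concentrated in marifolium 12 and 18. The 16 were picked for large changes or small p in these same libraries, so their staying is no independent support. Clusters that a setting leaves out do not enter. Only 5 of the 16 entered with clusters at 0 in all of a subspecies left out, and 12 with at least 1 CPM in 8 libraries. Sums per code kept 11 and lost Cluster-3823.43744, the largest increases in marifolium and origanifolium, the largest decrease in origanifolium, and a decrease in marifolium (adjusted p 0.0615, at 10.6 CPM in the others). The largest decrease in origanifolium was also lost with voom, and the largest increase in marifolium without marifolium 12 and 18. For clusters in 1 subspecies alone, a minimum of 20 gave 49, 31, 16 and 4 present (andalusicum, marifolium, molle, origanifolium) and 5, 6 and 4 absent (andalusicum, marifolium, molle). A minimum of 5 gave 57 present in origanifolium, with 22 absent in marifolium and 2 in origanifolium, and 1 absent in origanifolium with at most 1 count as absence. Without 1 library, present clusters ran from 113 to 125 in andalusicum, 83 to 754 in marifolium (highest without 15, then 259 without 17), 37 to 48 in molle and 33 to 45 in origanifolium, and absent ones from 14 to 17, 11 to 20, 9 to 15 and 0 to 2. Depth limits what absence can show, since each library's 0 allows up to 0.0879 to 0.135 CPM.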

Other observations

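The comparisons of clusters detected per library, of the pairings of subspecies with all their alternatives, of thinned counts and of title codes kept whole were chosen after seeing the data.

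Clusters with at least 1 count were most numerous in origanifolium. Its libraries had at least 1 count in 57352 ± 1181 clusters (SD, n = 4), against a mean of 48116 in the 12 others, and all 4 of its libraries had at least 55980, above the highest other library at 54634 (exact permutation test over all choices of 4 libraries, two-sided p = 0.00110, Benjamini-Hochberg adjusted p = 0.00440 over the 4 subspecies). That test treats libraries of the same title code as independent. With codes kept whole there are 28 choices, and the difference did not pass the adjustment (exact permutation test, two-sided p = 0.0357, the smallest it can give, adjusted p = 0.143). This was so although its libraries were the shallowest on average, and after thinning to equal depth the numbers were 56615 ± 768 against 47522. Clusters with at least 10 counts numbered 38971 ± 4531 in marifolium, 38779 ± 1075 in andalusicum, 38367 ± 1697 in origanifolium and 36557 ± 1746 in molle, so origanifolium was not the highest at that minimum. These numbers were not thinned to equal depth. In marifolium they were 44749 and 40418 in libraries 12 and 18, against 35339 and 35377 in 15 and 17. Clusters with at least 1 count were fewest in marifolium, 45086 ± 6352, which did not pass the adjustment with libraries taken as independent (two-sided exact permutation test, p = 0.0319, adjusted p = 0.0637) or with codes kept whole (p = 0.214, adjusted p = 0.429).

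Andalusicum and molle together stood apart from marifolium and origanifolium in 2775 clusters, 1618 higher and 1157 lower (edgeR, adjusted p under 0.05), and in 395 of them all 8 libraries of one side lay beyond all 8 of the other. The other ways of pairing the subspecies gave 356 clusters for andalusicum and marifolium against the rest and 211 for andalusicum and origanifolium against the rest. Presence and absence followed the same pairing, with 52 clusters counted in all libraries of one side and none of the other, against 4 and 2 for the other pairings. The counts of calls treat the libraries of a title code as independent. With the libraries of each code summed, edgeR called 221 clusters for the first pairing (134 higher, 87 lower), of which 210 were among the 2775, and 1 and 6 for the others, while 7378, 5511 and 4879 of the 46027 tested had an unadjusted p under 0.05. Limma voom with the code as a random block called 2921, 908 and 752, and DESeq2 called 6015, 3596 and 3034. For the first pairing the count also fell by over 1.5 times without origanifolium 31 (1755), 33 (1846), 38 (1824) or 39 (1734). Since 4 subspecies make only 3 pairings, no test over pairings can give a share under 0.05.

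Different depth does not account for the shared clusters, since 42 remained after thinning, against 4 for the next pairing. Variants of 1 transcript held as separate clusters, 1 for each side, would leave oppositely called partners of the same assembler gene, and 0% of the 52 clusters had one. Since only 7 had any other tested cluster of the same gene, this test had no way to come out in favour, and such variants cannot be told apart from other causes here. Mean distances between libraries followed the pairing only in part, since origanifolium lay nearer to molle (2.26) than to marifolium (2.32). Closer descent or a shared habitat of the paired subspecies stays open as a hypothesis that was not tested, because the labels give neither.

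More clusters were higher than lower in each subspecies against the other 3, with between 68.6% and 81.3% of edgeR calls upward. Clusters at 0 in all libraries of a subspecies made up 832 of 1393 higher calls in andalusicum and 422 of 709 in marifolium. In molle they were 520 of 904 and in origanifolium 565 of 1278. Of the lower calls they were 87 of 352, 169 of 325, 59 of 210 and 42 of 293 in the same order. Absence from another subspecies can be enough for a higher call, so the upward share is not one of raised expression alone. The share moved with the filter and the tool. Among clusters with at least 1 CPM in 8 libraries it was 60.0% in andalusicum, 60.2% in marifolium, 66.8% in molle and 68.7% in origanifolium, and without a filter on low counts it was 87.5%, 92.0%, 85.8% and 88.1%. With DESeq2 it was 54.6% in andalusicum and 57.0% in origanifolium, but 41.2% in marifolium and 46.8% in molle, where more clusters were lower. Summing counts per assembler gene left at least 69.2% upward in all 4 comparisons. Only 294, 144, 199 and 257 of the called clusters of andalusicum, marifolium, molle and origanifolium had another tested cluster of the same gene, and with all of these taken as higher and lost the share would still be at least 63.5%. The test thus had no way to come out in favour, and split variants cannot be told apart from other causes here. In simulated data with equal numbers of increases and decreases, 67.1% of the called changed clusters were increases. This was just under the lowest real share, 68.6% in marifolium. It was further below the 79.8% in andalusicum, 81.1% in molle and 81.3% in origanifolium. At 8-fold 36 increases and 19 decreases were called, at 32-fold 66 and 36, and at 64-fold 87 and 37, of 100 each. A greater power of the test for increases may thus account for part of this pattern. How much cannot be told apart from these simulated fold sizes, which were run on the clusters kept by filterByExpr alone.

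If libraries are taken as independent, chance can be excluded as the cause of the calls among the 4 subspecies together, but not for each comparison singly. In 100 regroupings of the 16 libraries into 4 groups of 4, only 1, the real one, gave as many clusters for each of the comparisons made. The highest of the other regroupings gave 1 cluster against the real 2661 among the 4 subspecies. It gave 4 against 1745 for andalusicum, 6 against 1034 for marifolium, 2 against 1114 for molle and 2 against 1571 for origanifolium, each compared with the rest. For every pair of subspecies it gave 1, against real counts from 124 to 988. For the pairings it gave 1 against 2775 (andalusicum and molle), 4 against 356 (andalusicum and marifolium) and 0 against 211 (andalusicum and origanifolium). The other regroupings mix libraries of different subspecies, so real differences between any subspecies add to the spread within groups. Calls for 1 subspecies, pair or pairing can thus be few there whether or not that comparison holds a difference. For these comparisons the numbers cannot exclude chance. These regroupings also part libraries of the same title code, which lie closer together, so for the same comparisons they do not exclude chance differences between codes either. For the 4 subspecies together, 100 ways of joining the 8 codes in pairs were fitted, and only 1, the real one, gave as many clusters. The highest of the others gave 1012 against the real 2661 and kept 2 of the subspecies intact, and the median of the others was 2. Chance joining of codes can thus be excluded for that count, and was not tested for the others.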
